A study of Mus musculus with 8 samples.

How the data were processed

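Total RNA of mouse cerebral cortex was measured on 8 Affymetrix arrays, 1 per sample, in 4 groups of 2 samples: vehicle, FGF2, FGF2 with U0126 and FGF2 with SB202190, per the labels. The deposited table held intensity values on a linear scale for 45101 probe sets, and the algorithm the authors used to make them was not given in the sources used here. On each array the mean of the values was 150.001 after 2% of them had been trimmed at each end, which shows a scaling of every array to a common mean. No detection calls were used. Nothing in the labels said that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

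Of the 45101 probe sets 34958 carried 1 gene symbol in the platform annotation, 932 several and 9211 none. Genes were named from the first kind alone, and a probe set with several symbols named none. The values were taken to log2(value + 1.77), where 1.77 is the 10th percentile of all values, and on this scale the difference between a pair of low signals is smaller than on a log2 scale without it. The arrays were then quantile normalized. A gene was represented by its probe set with the highest mean, and genes whose mean lay below the 40th percentile of all probe sets, a log2 value of 3.83, were left out, which left 13173 of 18193 genes. Log2 changes, their SE and p-values came from limma (version 3.58.1, in R 4.3.3) with all 8 arrays in 1 fit, moderated with an intensity trend (4 residual and 9.04 prior degrees of freedom), two-sided, and adjusted by Benjamini and Hochberg within each of the 6 comparisons. A gene was called at an adjusted p under 0.05. Signals are the deposited values with the SD over 2 arrays.

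Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the arrays. There were 40 lists, 32 of pathways or astrocyte states and 8 of cell types, of which 39 had at least 4 members above the filter and were tested. For each list the called members were also counted with p adjusted over the list alone. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 10 highest and 10 lowest called genes whose groups did not overlap in each of FGF2 against vehicle and each inhibitor against FGF2, 5 and 5 in the other comparisons, up to 4 members with the smallest p per list and comparison, and all members of the ERK and aryl hydrocarbon receptor lists. It took 381 genes, of which the text names a part as examples, mostly ones whose call held under the alternatives, so the counts of lost calls are given over all genes the rule took. Of the 381 genes 2 had another probe set called in the opposite direction, and neither is named.

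A gene was counted as called back by an inhibitor when FGF2 changed it and the inhibitor changed it the opposite way against FGF2. The share of the response moved back was the median inhibitor effect on the FGF2-changed genes, signed by the FGF2 response, as a percent of the median FGF2 response. Because both inhibitor comparisons share the FGF2 arrays, 100 sets were simulated with no inhibitor effect and with complete return to vehicle. Their noise was independent between genes and had the spread between replicates. A difference shared by both arrays of a group was therefore not simulated.

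The procedure was tested on simulated data made from the FGF2 and vehicle comparison with 13173 genes. It called 50.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 87.9% of those changed 4-fold in the right direction. Of 156 calls 11 were unchanged genes, and 0 changed genes were called in the wrong direction. The measured comparison had 4993 calls, and the adjusted p depends on the share of changed genes, so these rates need not hold for it. Of 100 genes made to return 67 were called back, beside 1 other gene. The shifted list had an adjusted p of 7.78e-55, and 0 of 38 other lists were called. The simulated noise was independent between genes, so this does not test how often camera calls lists of correlated genes.

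The alternatives were no normalization or median centring in place of quantiles, other pseudocounts, no filter or one at the 60th percentile, the variance prior without trend or made robust, array weights, only the arrays of a comparison, all probe sets or their mean per gene, leaving out probe sets that can bind several transcripts, other thresholds, genes selected on 1 replicate of each group and evaluated on the other, fry in place of camera, and leaving out each array. Figures were drawn with Python 3.11.15. Coordinates were not used, since the array's genome build was not given in the sources used here.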

Results

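Gene expression was measured in 8 samples of total RNA from mouse cerebral cortex, 1 array per sample. The series' title names the astroglial response to fibroblast growth factor-2 (FGF2), a mitogen for astrocytes and neural progenitors. The 4 groups of 2 samples were a vehicle control, FGF2, FGF2 with U0126 and FGF2 with SB202190. U0126 inhibits the MEK kinases that activate ERK, and SB202190 inhibits p38 kinases. Doses, times, whether the RNA came from cultured astrocytes or from tissue, and whether the samples came from separate cultures or animals were not given in the sources used here. The label of replicate 2 of FGF2 with SB202190 named the type of treatment acclimatization where all other labels had wait, with the same growth factor and inhibitor as replicate 1, and the sample was kept in its group. Each array had 45101 probe sets, and the median signal per array lay between 22.3 and 27.8. Across the 13173 genes tested, replicates correlated with r of 0.980 to 0.984 and arrays of different groups with r of 0.947 to 0.981. The ratio of the 3' to the 5' control probe sets, a sign of RNA quality, was 0.697 to 0.777 for Gapdh and 1.26 to 1.41 for Actb, where the arrays of FGF2 with U0126 had the lowest values, 1.28 and 1.26, and the others 1.31 to 1.41. Replicate 2 of FGF2 stood apart in the control transcripts added during labelling or hybridization, with signals of 9453 for cre, against 6829 to 7617 on the other arrays, and 312 for bioB, against 187 to 249. The first principal component held 42.8% of the variance and the second 19.3%. Changes are given below as log2 changes ± SE, with n = 2 arrays in every group, and signals as mean ± SD.

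The comparison of FGF2 with vehicle asked which genes answer to the growth factor. FGF2 raised genes of the cell cycle and of the ERK pathway. Of 29 mature astrocyte genes 21 were lower, in a list whose call was lost with an estimated correlation (adjusted p = 0.164 with an estimated correlation). Hmga2, a chromatin protein of proliferating progenitors, had a signal of 47.6 ± 10.3 with vehicle and 825 ± 7.35 with FGF2, a log2 change of 4.18 ± 0.12 (adjusted p = 6.87e-11). Esm1, a secreted proteoglycan, went from 110.4 ± 8.96 to 2001 ± 36.6, a log2 change of 4.17 ± 0.11. Fosl1, a subunit of the AP-1 transcription factor, rose by 3.26 ± 0.16. In the other direction Aqp4, the astrocyte water channel, fell from 5340.4 ± 228 to 1557 ± 48.6, a log2 change of -1.92 ± 0.06 (adjusted p = 8.82e-11). Elobl had the lowest log2 change among called genes, at -4.45 ± 0.08, with a signal of 5724 ± 532 with vehicle and 283 ± 23.6 with FGF2. The cytokine Il11 rose from 4.74 ± 4.46 to 93 ± 11.1, and the connexin Gjb2 fell from 145 ± 23.6 to 13.1 ± 3.19. At low signals the log2 change depends on the pseudocount, and that of Il11 was 4.22 ± 0.41 with the pseudocount of 1.77 and 2.47 with one of 16.

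Of 27 measured genes on the list of ERK feedback and target genes, 24 rose with FGF2, 0 fell and 3 did not pass the test (25 called when adjusted over the list alone). The median was 1.28 (adjusted p = 5.67e-16, and adjusted p = 0.0393 with an estimated correlation). Dusp6, a phosphatase that inactivates ERK, rose by 2.24 ± 0.07, its relative Dusp4 by 2.60 ± 0.17, and the feedback inhibitors Spry4 and Spry2 by 2.20 ± 0.21 and 1.28 ± 0.10. Egr1, an early transcription factor of this pathway, was not called, at -0.05 ± 0.09. Among DNA replication genes 28 of 29 rose and 0 fell (29 called when adjusted over the list alone). The median was 1.30 (adjusted p = 8.93e-17, and adjusted p = 0.0228 with an estimated correlation). The licensing factor Cdt1 rose by 2.12 ± 0.08, the helicase subunits Mcm5 and Mcm7 by 2.07 ± 0.10 and 1.21 ± 0.07, and Rrm2, a subunit of ribonucleotide reductase, by 1.48 ± 0.08. Of 29 mitosis genes 23 rose and 0 fell (25 adjusted over the list alone), among them the kinase Cdk1 by 0.99 ± 0.10 and the checkpoint kinase Bub1 by 2.04 ± 0.25. The median was 1.05 (adjusted p = 1.32e-08, and adjusted p = 0.0359 with an estimated correlation). Ribosome biogenesis and translation genes rose in 21 of 25 cases with none lower (25 adjusted over the list alone), including Fbl, the methyltransferase of ribosomal RNA, by 1.36 ± 0.09 and Npm1, a nucleolar protein, by 0.66 ± 0.05. The median was 0.66 (adjusted p = 2.12e-12, and adjusted p = 0.0359 with an estimated correlation).

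Of 29 mature astrocyte genes 21 fell with FGF2 and 3 rose (24 called when adjusted over the list alone). The median was -0.65 (adjusted p = 2.24e-08, and adjusted p = 0.164 with an estimated correlation). The gap junction protein Gja1 had a log2 change of -1.28 ± 0.06, the glycogen regulator Ppp1r3c of -1.64 ± 0.09 and the transcriptional inhibitor Id4 of -0.92 ± 0.06. Interferon-stimulated genes fell in 19 of 26 cases with 0 higher (21 adjusted over the list alone). The median was -0.60 (adjusted p = 1.09e-08, and adjusted p = 0.141 with an estimated correlation). Among them were the antiviral genes Ifit3 and Ifit1, at -1.69 ± 0.12 and -1.41 ± 0.11, and the GTPase Gbp2, at -1.15 ± 0.11. Of 13 pan-reactive astrocyte genes 8 fell and 2 rose (10 adjusted over the list alone). The median was -0.57 (adjusted p = 0.00655, and adjusted p = 0.167 with an estimated correlation). The intermediate filament Gfap fell by 0.65 ± 0.06, while the protease inhibitor Timp1 and the hyaluronan receptor Cd44 rose by 1.62 ± 0.08 and 0.99 ± 0.06. The list of potassium, chloride and calcium channels and pumps had 8 lower and 1 higher of 19 (10 adjusted over the list alone) and a median of -0.47 (adjusted p = 0.00655, and adjusted p = 0.157 with an estimated correlation). Among the lower ones was the inward rectifier Kcnj10 at -1.50 ± 0.12. So were the 2-pore-domain potassium channels Kcnk2 and Kcnk1 at -1.63 ± 0.12 and -1.05 ± 0.09.

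Genes of the unfolded protein and amino acid stress response rose in 12 of 25 cases and fell in 1 (14 adjusted over the list alone). The median was 0.28 (adjusted p = 0.00309, and adjusted p = 0.203 with an estimated correlation). The members with the smallest p made or imported amino acids: asparagine synthetase Asns rose by 2.32 ± 0.09, the transporter Slc7a5 by 2.07 ± 0.09 and the serine synthesis enzyme Phgdh by 1.25 ± 0.07. Neural progenitor and radial glia genes moved both ways, 7 higher and 7 lower of 20 (14 adjusted over the list alone). The list as a whole was not called (adjusted p = 0.628, and adjusted p = 0.653 with an estimated correlation). Within it the transcription factors Olig2 and Hes1 rose by 1.86 ± 0.08 and 1.52 ± 0.11, and the matrix protein Tnc by 1.73 ± 0.10. Secreted growth factors were likewise split, 8 higher and 4 lower of 23 (14 adjusted over the list alone; adjusted p = 0.378, and adjusted p = 0.503 with an estimated correlation). The EGF receptor ligand Hbegf had a change of 1.81 ± 0.05, and Igf1 and Angpt1 had -1.68 ± 0.14 and -1.86 ± 0.12.

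Markers of other cell types moved with FGF2 as well. Of 16 ependymal and choroid plexus genes 10 fell and 0 rose (12 adjusted over the list alone), led by the cilium genes Dynlrb2 at -2.05 ± 0.10, Cfap126 at -1.28 ± 0.07 and Foxj1 at -1.18 ± 0.09. The median was -0.85 (adjusted p = 7.97e-06, and adjusted p = 0.141 with an estimated correlation). Of 18 meningeal fibroblast and pericyte genes 13 fell and 1 rose (14 adjusted over the list alone), including the matrix genes Ogn at -1.55 ± 0.08 and Col1a2 at -1.15 ± 0.08. The median was -0.46 (adjusted p = 9.49e-06, and adjusted p = 0.28 with an estimated correlation). Of 5 measured genes of myelinating oligodendrocytes 4 fell and 0 rose. The lists of microglia, oligodendrocyte precursors, neurons and endothelial cells were not called, with medians of -0.05, -0.08, 0.22 and -0.15 (adjusted p = 0.994, 0.426, 0.628 and 0.417).

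In all, limma called 4993 of 13173 genes between FGF2 and vehicle, 2489 higher and 2504 lower. Of these 432 and 570 changed at least 2-fold. When each array was instead centred on the median of all its probe sets, 4017 genes were higher and 1479 lower, because this centring moved the median change of the genes tested to 0.16. Of 39 lists 17 were called by camera, and 4 of these held with an estimated correlation, namely ERK, DNA replication, mitosis and ribosome biogenesis. Among 172 called genes taken by the naming rule, 9 lost their call when some array was left out. With the mean of a gene's probe sets the log2 changes of Cdt1 and Col1a2 were 0.96 and -0.55, while Gfap had -0.35 with median centring.

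**Figure D1:**
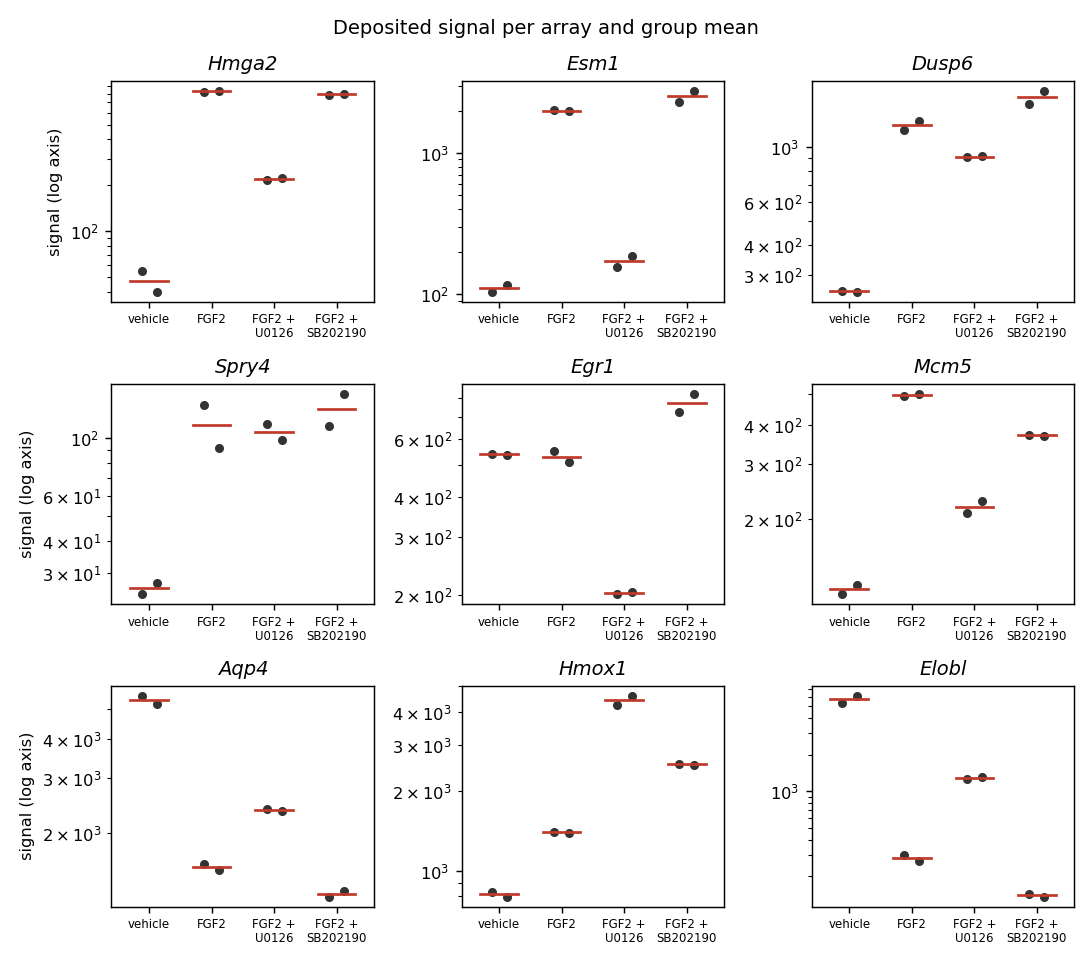
Deposited signal on a log axis for 9 genes, with 1 point per array and a red line at the mean of the 2 arrays of each group. The signal of Esm1 with FGF2 and U0126 lies near that with vehicle, that of Spry4 stays near its level with FGF2 alone, and Hmox1 has its highest signal with U0126.

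Adding U0126 to FGF2 asked which part of the response needs MEK. U0126 lowered cell cycle genes and raised genes of oxidative defence in comparison with FGF2 alone. Esm1 fell from 2001 ± 36.6 with FGF2 to 172 ± 22.1, a log2 change of -3.51 ± 0.11 (adjusted p = 1.33e-09). Serpinb2, an inhibitor of plasminogen activators, fell from 247 ± 10.5 to 25.8 ± 2.7, a change of -3.13 ± 0.17. Tgfbi, a matrix protein induced by TGF-beta, fell by 2.44 ± 0.11. In the other direction Cdsn, an adhesion protein, rose from 83.7 ± 22.2 to 591 ± 16.3, a change of 2.78 ± 0.16. Hmox1, the heme-degrading enzyme, rose from 1403 ± 10.1 to 4431 ± 236, a change of 1.66 ± 0.06 (adjusted p = 1.82e-09).

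With FGF2 alone 7 of 15 measured targets of NRF2, the transcription factor of oxidative defence, had risen against vehicle and 4 had fallen (12 adjusted over the list alone), and the list was not called (adjusted p = 0.205, and adjusted p = 0.503 with an estimated correlation). All 15 rose with U0126 (15 adjusted over the list alone). The median was 0.83 (adjusted p = 4.37e-19, and adjusted p = 0.0254 with an estimated correlation). The quinone reductase Nqo1 rose by 1.77 ± 0.10, the glutathione synthesis enzyme Gclm by 1.27 ± 0.07 and the sulfiredoxin Srxn1 by 1.24 ± 0.06. DNA replication genes fell in 21 of 29 cases with 0 higher (25 adjusted over the list alone), among them Rrm2 at -1.73 ± 0.08, Mcm6 at -1.23 ± 0.10 and Mcm7 at -0.91 ± 0.07. The median was -0.84 (adjusted p = 1.84e-16, and adjusted p = 0.0226 with an estimated correlation). Mitosis genes fell in 20 of 29 cases with 0 higher (22 adjusted over the list alone), among them the cyclin Ccna2 at -1.34 ± 0.16 and the proliferation marker Mki67 at -1.73 ± 0.22. The median was -0.88 (adjusted p = 3.22e-12, and adjusted p = 0.0226 with an estimated correlation).

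Of 27 ERK feedback and target genes 11 fell and 1 rose (15 adjusted over the list alone). The median was -0.38 (adjusted p = 1.56e-05, and adjusted p = 0.175 with an estimated correlation). The log2 change was -1.90 ± 0.12 for Hmga2, -1.37 ± 0.09 for Egr1, -1.04 ± 0.09 for the EGF receptor inhibitor Errfi1 and -1.09 ± 0.11 for the membrane protein Emp1, while Ier3, an early response gene, rose by 0.79 ± 0.08. The change was smaller for Dusp6, at -0.43 ± 0.07, and was not called for Dusp4, Spry4, Spry2, Etv5 or Fosl1, at -0.18 ± 0.17, -0.07 ± 0.21, -0.08 ± 0.10, -0.14 ± 0.08 and 0.23 ± 0.16. Fosl1 was called higher, at 0.54, without replicate 2 of FGF2 with U0126, and had -0.08 without replicate 1. BMP and TGF-beta target genes fell in 8 of 18 cases and rose in 1 (9 adjusted over the list alone), including Id3 at -0.60 ± 0.06 and Skil at -0.92 ± 0.09. The median was -0.22 (adjusted p = 6.68e-04, and adjusted p = 0.115 with an estimated correlation).

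Ependymal and choroid plexus genes rose in 8 of 16 cases with 0 lower (10 adjusted over the list alone), Cfap126 at 0.71 ± 0.07 and Dynlrb2 at 0.68 ± 0.10 among them. The median was 0.60 (adjusted p = 7.00e-04, and adjusted p = 0.177 with an estimated correlation). Genes of glycogen and glutamate handling rose in 8 of 13 cases with 0 lower (8 adjusted over the list alone; adjusted p = 1.56e-05, and adjusted p = 0.175 with an estimated correlation). The members with the smallest p, Gclm, Gclc at 0.55 ± 0.06 and the cystine transporter Slc7a11 at 1.08 ± 0.13, also stood on the NRF2 list. Of 4 measured targets of the aryl hydrocarbon receptor 3 rose (3 adjusted over the list alone; adjusted p = 2.75e-05, and adjusted p = 0.0928 with an estimated correlation). They were Cyp1b1, a cytochrome P450, at 1.42 ± 0.06, Tiparp at 0.78 ± 0.07 and Nqo1, which also stood on the NRF2 list. Mature astrocyte genes rose in 13 of 29 cases and fell in 2 (15 adjusted over the list alone), Aqp4 by 0.63 ± 0.06 (0.37 with the mean of its probe sets) and Gja1 by 0.42 ± 0.06 among them, while the bicarbonate transporter Slc4a4 fell by 1.04 ± 0.09. That list's median was 0.12 (adjusted p = 0.0196, and adjusted p = 0.367 with an estimated correlation). The call was lost without replicate 1 of FGF2 with U0126, at adjusted p = 0.0566, with no normalization and with median centring.

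Between FGF2 with U0126 and FGF2 alone limma called 2920 genes, 1537 higher and 1383 lower, between groups that also differed in the Actb ratio, 1.28 and 1.26 against 1.35 and 1.38, and 165 and 204 of them changed at least 2-fold. With centring on the kept genes, a setting chosen after the data were seen, 1289 were higher and 1661 lower. Without replicate 1 of FGF2, or replicate 2 with its high control transcripts, 1854 and 1787 genes were called, with the mean of a gene's probe sets 1781, and without the intensity trend in the variance prior 1619. Of 39 lists 15 were called by camera, and NRF2 targets, DNA replication and mitosis held with an estimated correlation. Among 162 called genes taken by the naming rule, 23 lost their call when some array was left out.

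Adding SB202190 asked the same of p38. SB202190 changed 398 genes against FGF2 alone, 14 of them at least 2-fold. Nupr1, a stress-induced chromatin protein, had a log2 change of -1.51 ± 0.09 (adjusted p = 3.07e-06). Elobl fell by 1.00 ± 0.08, and Tgfbi fell by 1.13 ± 0.11, a call that was lost without the probe sets that can bind several transcripts. Ier3 rose from 763 ± 39.5 to 1763 ± 134, a change of 1.20 ± 0.08 (adjusted p = 8.20e-06). Gadd45a, a DNA damage response gene that also acts upstream of p38, rose from 696 ± 23.8 to 1360.5 ± 37.6, a change of 0.97 ± 0.07. The methyltransferase Inmt fell by 1.06 ± 0.12.

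NRF2 targets rose in 9 of 15 cases with 0 lower (11 adjusted over the list alone), including Hmox1 at 0.83 ± 0.06, Srxn1 at 0.54 ± 0.06 and the thioredoxin reductase Txnrd1 at 0.45 ± 0.05. The median was 0.44 (adjusted p = 1.69e-12, and adjusted p = 0.0486 with an estimated correlation). BMP and TGF-beta target genes fell in 7 of 18 cases with 0 higher (7 adjusted over the list alone), Tgfbi and Id3 at -0.57 ± 0.06 among them. The median was -0.34 (adjusted p = 5.84e-07, and adjusted p = 0.0486 with an estimated correlation). Of 29 DNA replication genes 3 fell and 0 rose over all genes tested, against 13 adjusted over the list alone. The median was -0.30 (adjusted p = 5.20e-10, and adjusted p = 0.0486 with an estimated correlation). The 3 were Mcm5 at -0.42 ± 0.10, Mcm7 at -0.35 ± 0.07 and the polymerase clamp Pcna at -0.21 ± 0.05. Of 20 genes of cholesterol synthesis 4 rose and 0 fell (9 adjusted over the list alone), namely the sterol regulator Insig1 at 0.50 ± 0.08 and the synthesis enzymes Hmgcs1 at 0.31 ± 0.06, Cyp51 at 0.33 ± 0.08 and Msmo1 at 0.34 ± 0.07. The median was 0.24 (adjusted p = 2.76e-06, and adjusted p = 0.0486 with an estimated correlation). Of 29 mitosis genes 1 fell, Cdc20 at -0.61 ± 0.15 (2 adjusted over the list alone). The median was -0.34 (adjusted p = 8.77e-05, and adjusted p = 0.0514 with an estimated correlation). Each of the 8 calls of these DNA replication, cholesterol and mitosis genes was lost without replicate 1 of FGF2, replicate 2 of FGF2 and replicate 2 of FGF2 with SB202190, where Mcm5 had -0.43, -0.40 and -0.42 and Insig1 0.50, 0.50 and 0.40. With the mean of their probe sets Mcm5 had -0.68 and Cdc20 -0.22, and neither was called.

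Among 27 ERK feedback and target genes 5 rose and 0 fell (5 adjusted over the list alone). The median was 0.07 (adjusted p = 0.00413, and adjusted p = 0.307 with an estimated correlation). Beside Ier3, Egr1 rose by 0.54 ± 0.09 and Dusp6 by 0.36 ± 0.07. The list's call was lost without replicate 2 of FGF2 with SB202190 (adjusted p = 0.0514) and with the mean of a gene's probe sets. Without that array Egr1, Dusp6 and Dusp1 had 0.43, 0.28 and 0.26 and were not called. Nor were they without replicate 2 of FGF2, at 0.49, 0.42 and 0.28, and Dusp6 and Dusp1 also lost their call without replicate 1, at 0.31 and 0.36. Of 23 p38 pathway genes 2 rose, Gadd45a and the phosphatase Dusp1 at 0.32 ± 0.07, and 0 fell (3 adjusted over the list alone). The list was not called (adjusted p = 0.133, and adjusted p = 0.307 with an estimated correlation). Markers of meningeal fibroblasts and pericytes had a median of -0.16 with 1 of 18 called, Crabp2 at -0.92 ± 0.13 (3 adjusted over the list alone; adjusted p = 0.0076, and adjusted p = 0.359 with an estimated correlation). The list lost its call without replicate 2 of FGF2, at adjusted p = 0.0715, and without replicate 2 of FGF2 with SB202190, at adjusted p = 0.280.

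Of the 398 genes that limma called, 174 were higher and 224 lower, with 5 and 9 of them changed at least 2-fold. The count fell to 84, 82 and 101 without replicate 1 of FGF2, replicate 2 of FGF2, the array with high control transcripts, or replicate 2 of FGF2 with SB202190, the sample with the different label. It was 235 with median centring, 124 higher and 111 lower, and 170 with the mean of a gene's probe sets. Without the intensity trend limma called 0 genes, with 1820 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0765. Of the 91 called genes taken by the naming rule 69 lost their call when some array was left out. Of 39 lists 16 were called by camera, and NRF2 targets, DNA replication, BMP and TGF-beta targets and cholesterol synthesis held with an estimated correlation. Some of the 16 lists lost their call when an array was left out.

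**Figure D2:**
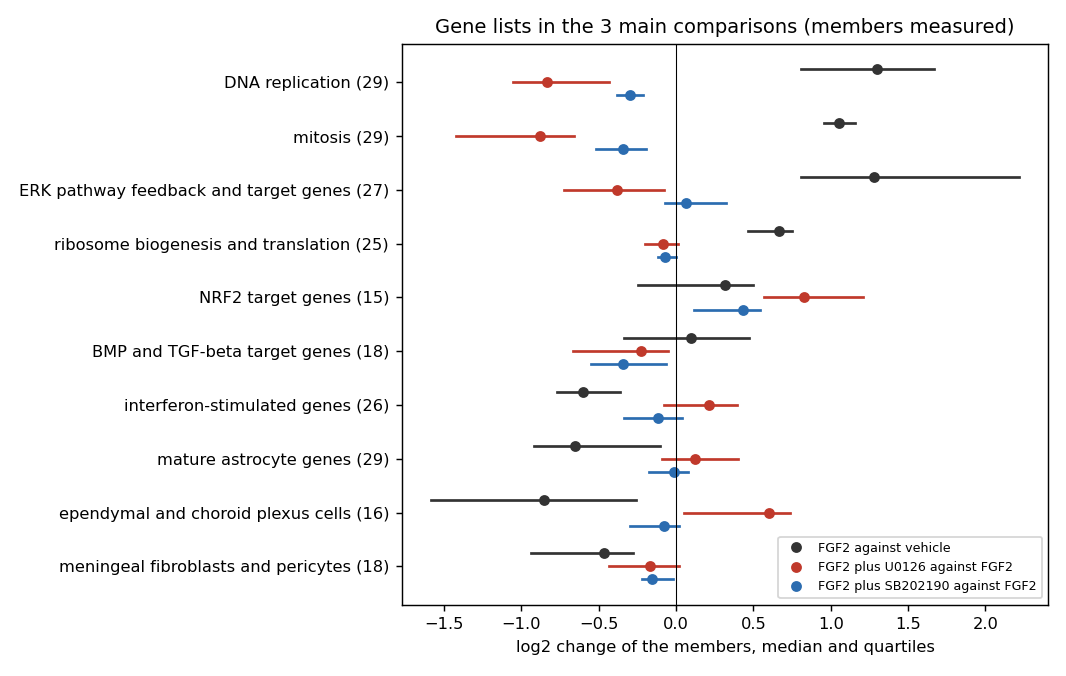
Median log2 change of the measured members of 10 gene lists, with bars from the first to the third quartile, for FGF2 against vehicle (black), FGF2 with U0126 against FGF2 (red) and FGF2 with SB202190 against FGF2 (blue). DNA replication and mitosis have medians of 1.30 and 1.05 with FGF2 and of -0.84 and -0.88 when U0126 was added.

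How much of the FGF2 response each inhibitor took back was counted as genes called in the opposite direction to FGF2. No array had an inhibitor without FGF2, so such a change may also be an effect of the compound or its solvent that does not need FGF2. Against FGF2 alone U0126 also changed 990 genes that FGF2 had not changed, and SB202190 112. With U0126 1687 of the 4993 FGF2-changed genes were called back, or 33.8%, of which 818 had been raised by FGF2 and 869 lowered. With SB202190 161 were called back, or 3.22%, 80 raised and 81 lowered. Other FGF2-changed genes were called further the same way, 243 with U0126 and 125 with SB202190. Of the former 138 had been raised and 105 lowered by FGF2, and of the latter 31 and 94. Cell cycle genes such as Rrm2 and Mki67 and the secreted Esm1 were among those that fell with U0126, and Aqp4 and Gja1 among those that rose. The inhibitors' median effect on the FGF2-changed genes, taken along the direction of the FGF2 response, amounted to 35.8% of its median with U0126 and 11.3% with SB202190. With genes selected on 1 replicate of each group and evaluated on the other, the latter share was 8.87% and 4.95%. Selected on replicate 2 and evaluated on replicate 1, the shares of both inhibitors moved by at least the SD between the replicates' shares. The range of the share with U0126 over all settings is given below. Because the same FGF2 arrays enter both comparisons, 100 simulated sets with no inhibitor effect gave on average 0.24 genes called back (highest 3) and 3.43% of the response. Simulated sets with a complete return to the vehicle level gave 95.1%. Without replicate 1 or 2 of FGF2, 1105 and 1084 genes were called back with U0126 and 37 and 31 with SB202190. The latter count was 36 without replicate 2 of FGF2 with SB202190, and without the intensity trend limma called back 972 and 0.

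Both inhibitors raised 77 genes over FGF2 alone and lowered 93, where independent lists would share 20.3 and 23.5, and simulated sets with no effect gave on average 0.07 genes called the same way. Across genes, which are not independent replicates, the 2 sets of changes correlated with r = 0.364 against a simulated 0.499. Their covariance was 0.0539 against 0.0322 simulated, a difference of 0.0217. Part of the overlap beyond that of independent lists may come from the shared FGF2 arrays, since 2 arrays could not be split into sets of at least 2 for each comparison. The counts fell to 26 and 23 without replicate 1 of FGF2, to 32 and 15 without replicate 2 and to 30 and 29 without replicate 2 of FGF2 with SB202190. The 93 lowered genes became 48 without replicate 1 of that group and 44 with median centring, both counts were 41 with the mean of a gene's probe sets, and both were 0 without the intensity trend, where limma called no gene with SB202190 (1820 at an unadjusted p under 0.05). Hmox1, Srxn1 and Cyp1b1 were among the genes that rose with both, the last by 0.65 ± 0.06 with SB202190 (not called with the mean of its probe sets). Tgfbi and Id3 were among those that fell with both.

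FGF2 with U0126 was compared with vehicle to see what remained of the response. Most ERK and translation genes were higher than with vehicle, in lists whose calls were lost with an estimated correlation (adjusted p = 0.0772 for both with an estimated correlation). Mthfd2, an enzyme of mitochondrial folate metabolism, rose from 50.8 ± 9.49 to 499 ± 80.4, a log2 change of 3.35 ± 0.18 (adjusted p = 1.99e-08), and Fosl1 by 3.49 ± 0.16. Inmt fell from 1437 ± 62.5 to 99.7 ± 8.13, a change of -3.83 ± 0.12 (adjusted p = 2.32e-10). Of 27 ERK feedback and target genes 20 were higher and 1 lower (23 adjusted over the list alone), among them Dusp6 at 1.81 ± 0.07, Spry4 at 2.12 ± 0.21 and Hmga2 at 2.28 ± 0.12. The median was 0.96 (adjusted p = 2.86e-10, and adjusted p = 0.0772 with an estimated correlation). Of the 24 members that FGF2 had raised 19 were also higher here, and Errfi1, Emp1, Il17rd, Egr3 and Elk3 were not called, at -0.05 ± 0.09, -0.08 ± 0.11, 0.11 ± 0.27, -0.61 ± 0.25 and 0.25 ± 0.10. Il17rd had 0.64 without replicate 1 of vehicle and -0.41 without replicate 2, uncalled in both, and its rise with FGF2 was lost, among other settings, without replicate 2 of vehicle (0.29) and without either FGF2 array, as was that of Egr3 without replicate 2 of vehicle (0.68), without replicate 1 of FGF2 (0.62) and with the mean of its probe sets (0.55). Elk3 was called higher with median centring of all probe sets (0.47) and without either FGF2 array (0.25), and Egr3 lower without normalization (-0.81) and with centring on the kept genes (-0.81). Egr1 was the lower one, at -1.42 ± 0.09. Ribosome biogenesis and translation genes were higher in 21 of 25 cases with 0 lower (22 adjusted over the list alone). The median was 0.55 (adjusted p = 5.83e-11, and adjusted p = 0.0772 with an estimated correlation). NRF2 targets were higher in 12 of 15 with 0 lower (12 adjusted over the list alone). The median was 1.06 (adjusted p = 2.55e-12, and adjusted p = 0.0772 with an estimated correlation). Mature astrocyte genes were lower in 19 of 29 cases with 0 higher (20 adjusted over the list alone), Aqp4 at -1.29 ± 0.06 among them. The median was -0.40 (adjusted p = 3.26e-09, and adjusted p = 0.113 with an estimated correlation). Meningeal markers were lower in 15 of 18 cases and higher in 1 (17 adjusted over the list alone). The median was -0.89 (adjusted p = 3.13e-10, and adjusted p = 0.113 with an estimated correlation). Ependymal markers were lower in 7 of 16 and higher in 1 (8 adjusted over the list alone). The median was -0.48 (adjusted p = 8.85e-04, and adjusted p = 0.135 with an estimated correlation). limma called 4179 genes, 2197 higher and 1982 lower, and with median centring of all probe sets 4029 higher and 1014 lower, with the median change at 0.19. Of the FGF2-changed genes 2768 were still called in the same direction against vehicle, where complete return gave 0.31 on average in simulated sets. Of 39 lists 19 were called and 0 held with an estimated correlation.

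FGF2 with SB202190 differed from vehicle in 4723 genes, beside 4993 for FGF2 alone. Esm1 rose from 110.4 ± 8.96 to 2528 ± 312, a log2 change of 4.51 ± 0.11 (adjusted p = 1.77e-11). Elobl fell from 5724 ± 532 to 139.6 ± 5.1, a change of -5.45 ± 0.08 (adjusted p = 6.59e-14). Of 27 ERK feedback and target genes 26 were higher and 0 lower (26 adjusted over the list alone). The median was 1.42 (adjusted p = 2.74e-19, and adjusted p = 0.0449 with an estimated correlation). DNA replication genes were higher in 24 of 29 cases (25 adjusted over the list alone). The median was 0.86 (adjusted p = 4.96e-12, and adjusted p = 0.0449 with an estimated correlation). Mitosis genes were higher in 13 of 29 (17 adjusted over the list alone). The median was 0.78 (adjusted p = 3.19e-05, and adjusted p = 0.068 with an estimated correlation). Mature astrocyte genes were lower in 21 of 29 cases and higher in 3 (24 adjusted over the list alone). The median was -0.71 (adjusted p = 2.36e-09, and adjusted p = 0.124 with an estimated correlation). Interferon-stimulated genes were lower in 20 of 26 (22 adjusted over the list alone). The median was -0.75 (adjusted p = 2.23e-10, and adjusted p = 0.103 with an estimated correlation). Foxj1 fell by 1.87 ± 0.09, and the ependymal list had 10 of 16 lower (11 adjusted over the list alone; adjusted p = 2.88e-06, and adjusted p = 0.106 with an estimated correlation). Cyp1b1 was called lower, at -0.20 ± 0.06. This call was lost without normalization, with the mean of its probe sets, without replicate 1 of vehicle (-0.16) and without replicate 2 of FGF2 with SB202190 (-0.13), and the sign turned with median centring of all probe sets. limma called 2378 genes higher and 2345 lower, and with median centring of all probe sets 4058 higher and 1436 lower, with the median change at 0.18. Of the FGF2-changed genes 3785 were still called in the same direction. Of 39 lists 19 were called, of which ERK, DNA replication and ribosome biogenesis held with an estimated correlation.

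The direct comparison of the inhibitors tests their difference and shares no array with FGF2 against vehicle. Esm1 had a signal of 172 ± 22.1 with U0126 and 2528 ± 312 with SB202190, a log2 difference of -3.84 ± 0.11 (adjusted p = 2.07e-10). Serpinb2 and the lipase inhibitor Angptl4 were lower with U0126, at -3.78 ± 0.17 and -2.60 ± 0.14. Elobl was higher with U0126, by 3.17 ± 0.08, as was Acox2, a peroxisomal oxidase, by 2.89 ± 0.26. Of 27 ERK feedback and target genes 14 were lower with U0126 and 0 higher (16 adjusted over the list alone), including Egr1 at -1.91 ± 0.09, Egr3 at -2.70 ± 0.25 and Errfi1 at -1.20 ± 0.09. The median was -0.41 (adjusted p = 2.53e-09, and adjusted p = 0.104 with an estimated correlation). DNA replication genes were lower in 14 of 29 cases and higher in 1 (17 adjusted over the list alone). The median was -0.44 (adjusted p = 1.55e-07, and adjusted p = 0.0599 with an estimated correlation). Mitosis genes were lower in 15 of 29 and higher in 1 (17 adjusted over the list alone), among them Ccna2 at -1.12 ± 0.16. The median was -0.52 (adjusted p = 2.21e-06, and adjusted p = 0.0599 with an estimated correlation). NRF2 targets were higher with U0126 in 13 of 15 cases with 0 lower (15 adjusted over the list alone). The median was 0.45 (adjusted p = 5.49e-12, and adjusted p = 0.0599 with an estimated correlation). Ependymal markers were higher in 8 of 16 and lower in 1 (9 adjusted over the list alone), Cfap126 and Foxj1 at 1.13 ± 0.07 and 1.13 ± 0.09 among them. The median was 0.82 (adjusted p = 1.50e-04, and adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes were higher in 11 of 26 cases with 0 lower (11 adjusted over the list alone), Ifit3 at 1.00 ± 0.12 among them. The median was 0.30 (adjusted p = 2.36e-04, and adjusted p = 0.197 with an estimated correlation). limma called 2989 genes, 1633 higher and 1356 lower with U0126, and with centring on the kept genes 1348 higher and 1603 lower. Of 39 lists 15 were called and 0 held with an estimated correlation. Of the 2489 genes FGF2 raised 657 were lower with U0126 than with SB202190 and 222 higher, and of the 2504 it lowered 796 were higher and 159 lower. Among the 8180 other genes 615 were higher and 540 lower. The count of called genes fell to 1813 without replicate 2 of FGF2 with SB202190, to 1784 with the mean of a gene's probe sets, which also moved Angptl4 and Egr3 to -1.60 and -1.44, and to 1729 without the intensity trend.

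**Figure D3:**
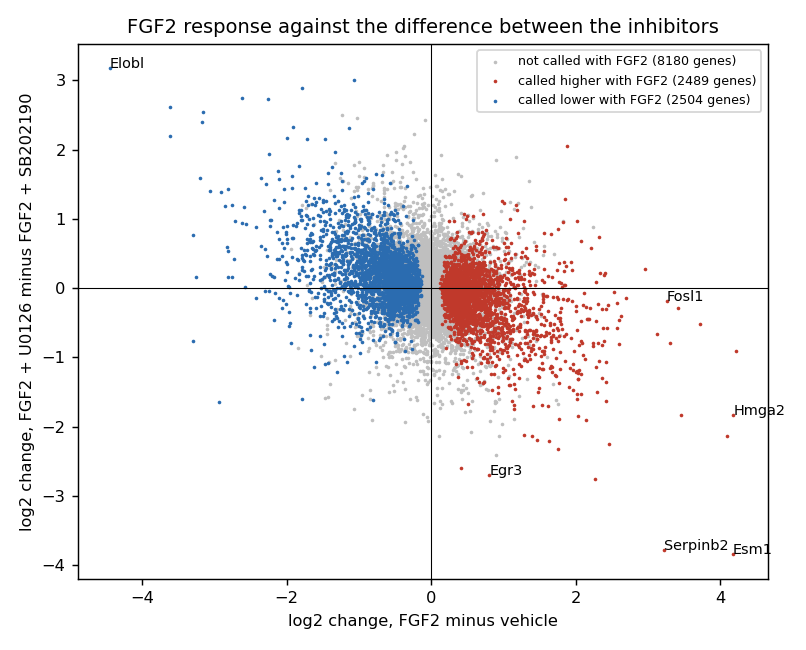
Log2 change with FGF2 against vehicle (horizontal) and log2 difference between FGF2 with U0126 and FGF2 with SB202190 (vertical), 1 point per gene and 13173 genes, which share no array. The 2489 genes called higher with FGF2 are red, the 2504 called lower blue and the 8180 others grey, and 6 genes are named.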

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

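The tests of each explanation were chosen only after the results they bear on had been seen, though some use fits without 1 array that were planned before, and the counts of opposite and unnamed changes came from rules fixed earlier. The SE of a list's median, or of a difference between medians, came from 2000 bootstrap draws of the members with all arrays in the fit. It treats genes as independent and holds no spread between arrays, so 2 SE is no test over samples. The limit of 3 SE for single ERK genes used the spread between arrays.

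Against FGF2 alone 76 genes were called in opposite directions with the 2 inhibitors, 23 lower with U0126 and higher with SB202190 and 53 the other way. That all 76 were also called between the inhibitors follows from this choice of genes and adds no support. The count was 10, 13 and 15 without replicate 1 of FGF2, replicate 2 of FGF2 or replicate 2 of FGF2 with SB202190, 39 with median centring of all probe sets, 28 with the mean of a gene's probe sets and 0 without the intensity trend, where limma called no gene with SB202190 (1820 at an unadjusted p under 0.05). Egr1 and Dusp6 were among them, with log2 changes of -1.37 ± 0.09 and -0.43 ± 0.07 with U0126 and 0.54 ± 0.09 and 0.36 ± 0.07 with SB202190. The latter calls were lost without replicate 2 of FGF2, at 0.49 and 0.42, and without replicate 2 of FGF2 with SB202190, at 0.43 and 0.28, and that of Dusp6 also without replicate 1 of FGF2, at 0.31. Among 3113 bright probe sets without a single gene name, which no gene result uses, 686 were called between FGF2 and vehicle, 417 higher and 269 lower.

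Of 24 ERK feedback and target genes that FGF2 had raised, 19 were also called above vehicle with FGF2 and U0126, and 5 were not (for the whole list adjusted p = 2.86e-10, and adjusted p = 0.0772 with an estimated correlation). Over 17 settings, that of the report included, 21 to 25 were raised, 17 to 21 were also above vehicle and 2 to 6 were not, and Il17rd, 1 of the 5 with 0.11 ± 0.27, had 0.64 without replicate 1 of vehicle and -0.41 without replicate 2. As for U0126 without any effect on its arrays, 1687 FGF2-changed genes were called back where simulated sets reached at most 3. Those sets held only the spread between replicates, so a difference shared by both arrays of a group stays open. Chance low signals on 1 vehicle array are argued against, since the lower of the list medians without either vehicle array was 0.998 (SE 0.266). A block that took back 1 common share of every member's response is argued against only if U0126 acted on the FGF2 response alone. No array had U0126 without FGF2, so that could not be checked. Of 24 FGF2-raised members 8 lay over 3 SE from the best common share of 23.9%, and 7 to 13 over the settings. In all 17 Spry1, Errfi1, Emp1 and Hmga2 lost more than the common share, and Fosl1 and Ier3 lay on the other side of it. In the setting of the report the latter did not fall with U0126, with changes of 0.23 (not called) and 0.79 against FGF2 alone. Egr3 and Elk3 lay over 3 SE away in 12 and 16, where a member was counted only in settings in which FGF2 raised it. Input to these genes that does not need MEK and an incomplete block with different sensitivity per gene may each account for this. So may an effect of the compound that does not need FGF2. None of these was tested, since no dose, measure of ERK activity or array with U0126 and no FGF2 was used here.

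NRF2 target genes were higher with both inhibitors than with FGF2 alone, 15 and 9 of 15. A return of genes that FGF2 had lowered is argued against as the whole cause, since FGF2 had lowered 4 of the 15, and the median of the other 11 was 1.08 (SE 0.227) with U0126 and 0.447 (SE 0.118) with SB202190. It stays open for the 4, of which 4 rose with U0126 and 1 with SB202190. Chance low signals on 1 FGF2 array are argued against, since the lower medians without either FGF2 array were 0.772 (SE 0.185) with U0126 and 0.391 (SE 0.131) with SB202190. An effect of the compounds or their solvent that does not need FGF2 may account for the rise and cannot be told apart from an effect on FGF2 signalling, because 0 arrays had an inhibitor and no FGF2.

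Markers of ependymal and meningeal cells were lower with FGF2, in 10 of 16 and 13 of 18 cases (adjusted p = 0.141 and adjusted p = 0.28 with an estimated correlation). If the share of all other cell types had fallen alike, every type's markers would have fallen alike. The comparison was with markers of microglia, oligodendrocyte precursors, neurons and endothelial cells, and left out those of myelinating oligodendrocytes. With a vehicle signal of at least 100, ependymal and meningeal medians differed from theirs by -1.08 (SE 0.598) and -0.766 (SE 0.535). Neither lay beyond 2 SE, although over all members, dim ones included, the differences of -0.88 (SE 0.369) and -0.493 (SE 0.246) did. Whether these types fell alike was therefore not decided. A lower share of ependymal or meningeal cells and a lower expression per cell cannot be told apart by this difference, since each array measured a whole sample. The meningeal list shares 5 of its genes with the extracellular matrix list. Foxj1 and Dynlrb2 had signals of 796 ± 8.69 and 1038 ± 93.7 with vehicle and Col1a2 of 2269.7 ± 171.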

How the results depend on the processing

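The pseudocount of 16 and centring on the kept genes were chosen after seeing the data, as were all settings for the counts of genes called with both inhibitors and for the common share of the ERK genes, and all others before. Low signals limit what could be seen: below a signal of 12.4 genes were left out. Leaving out 1 array left its group with 1, which is assumed to vary like the other groups. All 6 counts of called genes and both counts of genes moved back stayed within 1.5 times the value in the report with no normalization, centring on the kept genes, other pseudocounts, other filters, a robust prior, array weights, only the arrays of a comparison and no probe sets that can bind several transcripts. Over all genes that the naming rule took, 27 values that were called before or after the change of setting turned sign, 17 with the mean of a gene's probe sets, 8 with median centring of all probe sets and 2 without probe sets that can bind several transcripts. Unless a setting's construction shows it, the cause was not tested.

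With median centring of all probe sets 235 genes were called between SB202190 and FGF2 alone, 78 FGF2-changed genes were moved back by SB202190, oxidative phosphorylation had medians of 0.28 with FGF2 and 0.22 with FGF2 and SB202190 against vehicle in place of values below 0, and Cyp1b1 had 0.0578 with FGF2 and SB202190 against vehicle. Without the intensity trend the counts were 1619 for U0126 against FGF2, 0 for SB202190 against FGF2 (limma, 1820 at an unadjusted p under 0.05) and 1729 between the inhibitors, with 972 and 0 genes moved back. With all 27024 probe sets above the filter tested, and so more tests, the counts were of probe sets and not of genes, with unnamed ones included. Of these 8241 were called for FGF2 against vehicle, 4419 for U0126 against FGF2, 6701 and 7839 for U0126 and SB202190 against vehicle and 4513 between the inhibitors. With the mean of a gene's probe sets the counts were 1781 and 170 for U0126 and SB202190 against FGF2 and 1784 between the inhibitors, with 1020 and 65 genes moved back.

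At an adjusted p under 0.10 SB202190 against FGF2 had 791 calls and moved back 390 genes. With a 2-fold change also required, by construction fewer were called: 1002 for FGF2 against vehicle, 369 and 14 for U0126 and SB202190 against FGF2, 650 and 1008 for them against vehicle and 375 between them, with 199 and 5 genes moved back. By fry, which does not set a list against other genes, heat shock genes had a direction opposite to that by camera, which did not call them, in FGF2 against vehicle (median 0.19), U0126 against FGF2 (-0.13), U0126 and SB202190 against vehicle (-0.17 and 0.0745) and between the inhibitors (-0.17), and so had neural progenitor genes in U0126 against vehicle (-0.0188).

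When each of the 8 arrays was left out in turn, 3845 to 5021 genes were called for FGF2 against vehicle, 1787 to 2927 and 82 to 398 for U0126 and SB202190 against FGF2, 3135 to 4082 and 3671 to 4743 for them against vehicle and 1813 to 3011 between them, and 1084 to 1655 and 31 to 167 genes were moved back. The lowest counts against FGF2 came without replicate 2 of FGF2, and the lowest between the inhibitors without replicate 2 of SB202190. The percent of the FGF2 response moved back ranged over all settings from 26.9 to 40.2 with U0126 and from 4.95 to 13.3 with SB202190.

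No effect shared by samples of the same replicate number was seen, since replicate differences correlated at -0.0257 to 0.0337 over 6 pairs of groups. Whether the numbers paired the samples is not known, because the labels did not say what a number shares. With the number as a block 4971 genes were called for FGF2 against vehicle, 2906 and 412 for U0126 and SB202190 against FGF2, 4162 and 4698 for them against vehicle and 2993 between them, and 1667 and 172 genes were moved back.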

Other observations

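The list of unfolded protein and amino acid stress genes moved both ways when U0126 was added to FGF2, 10 members higher and 9 lower of 25 (23 adjusted over the list alone), and as a whole was not called (adjusted p = 0.661, and adjusted p = 0.756 with an estimated correlation). The tests are those of the report, and this list was singled out only after its values had been seen. Trib3, a pseudokinase induced by amino acid shortage, was called higher (adjusted p = 7.94e-04), with array signals of 20.8 and 2.74 with FGF2 and 181 and 89.6 with U0126 added, of which the low ones leave the size of the change open. The transcription factor Atf3 rose by 1.57 ± 0.34. It had 0.90 without replicate 1 of FGF2 and was not called without the intensity trend. The cystine transporter Slc7a11 rose by 1.08 ± 0.13. Among the lower members were the chaperones Hspa5 at -0.60 ± 0.06, Calr at -0.63 ± 0.06 and Hsp90b1 at -0.50 ± 0.06. Between the inhibitors 11 members were higher with U0126 and 4 lower (15 adjusted over the list alone; adjusted p = 0.0802, and adjusted p = 0.435 with an estimated correlation).

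The cell cycle lists were also compared between FGF2 with U0126 and vehicle. Of 29 DNA replication genes 14 were higher than with vehicle and 1 lower (15 adjusted over the list alone), with a median of 0.38 (adjusted p = 3.87e-05, and adjusted p = 0.0772 with an estimated correlation). Of 29 mitosis genes 5 were higher and 0 lower (3 adjusted over the list alone), with a median of -0.09, and the list was not called (adjusted p = 0.773, and adjusted p = 0.825 with an estimated correlation). The difference between the lists was not tested. Cdk1 was higher than with vehicle, by 0.45 ± 0.10, and Cdt1 by 1.71 ± 0.08 (1.13 with the mean of its probe sets).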
